A study of Homo sapiens with 12 samples.

How the data were processed

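RNA was measured in HCT116 cells, a human colorectal carcinoma line. The 12 samples fall into 4 groups of 3: parental cells, AGO2 knockout cells, and knockout cells that carry either wild-type or 5xA mutant AGO2 with an FH tag. Per the labels, each group was grown in triplicate wells seeded with 500000 cells and harvested after 48 h, total RNA was depleted of ribosomal RNA, and stranded libraries were run on an Illumina NextSeq instrument. The groups are called parental, knockout, FH-WT and FH-5xA here.

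The values used were 5 tables of the authors' own comparisons, each over the same 15074 Ensembl genes and each comparing 6 libraries: knockout against parental, FH-WT and FH-5xA against knockout, and FH-WT and FH-5xA against parental. Per the file headers, the deposited tables give a log2 fold change, a mean expression as log2 CPM (counts scaled to library size) that is identical in all 5 tables, a likelihood ratio score, a p-value and a false discovery rate. TopHat2 2.0.12, Cufflinks 2.2.1, featureCounts 1.4.6 and edgeR 3.8.6 were used by the authors, per the submitters' processing notes, on the hg38/GRCh38 build. The gene annotation, the filter on low counts, the normalization factors and whether counting used strand are not given in the sources used here. The deposited p-value equalled the upper tail of a chi-square distribution with 1 degree of freedom at the deposited score, to within 7.36e-15. Fold changes closed across tables to within 4.62e-14 on the log2 scale.

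Counts per library were not analysed here. The depth of each library is therefore unknown, and the tests planned on counts gave way to the deposited tests. No library was left out in turn, no labels were permuted and no replicate block was fitted. A standard error (SE) was derived for every fold change as its absolute log2 value divided by the square root of the deposited score. Its median was 0.117 for knockout against parental and 0.122 for FH-WT against knockout; over all tables it was 0.262 for genes with mean expression under 1 (log2 CPM) and 0.0845 for genes at 6 or more. The p-values measure the spread between wells of a single line per group, not between independently made lines.

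No table compared FH-5xA with FH-WT. Their log2 difference was taken as FH-5xA against knockout minus FH-WT against knockout, with a variance obtained by solving the 5 squared SEs for the variance of each group; the chi-square test with 1 degree of freedom was adjusted over 15072 genes by the Benjamini-Hochberg method. In 2 genes the difference was undefined. The same derivation was checked by predicting FH-WT against knockout from the other 4 tables: it called 1511 genes against 1516 in the deposited table, with 1507 shared. It was also tested on simulated counts for 15074 genes, with 3 libraries per group and equal assumed depths, in which 200 genes differed between FH-5xA and FH-WT. It recovered 69.0% of the 100 genes changed by 0.5 and 91.0% of the 100 genes changed by 1 on the log2 scale, with 6 false calls among 166.

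Genes were called at a false discovery rate under 0.05. The named genes were, for each comparison, the 10 largest rises and 10 largest falls among called genes with mean expression of at least 1 CPM, the 11 core genes AGO1 to AGO4, TNRC6A, TNRC6B, TNRC6C, DICER1, ANKRD52, PPP6C and CSNK1A1, and up to 4 members of each gene list with the smallest p. This rule, 32 gene lists with 616 entries, 26 microRNA seed families and the comparisons were chosen before the data were examined. Symbols were found for 14974 of the identifiers in a symbol table, and 15029 were in GENCODE 29 (GRCh38), which gave positions, gene types, transcripts and 3′ untranslated regions (UTRs).

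The lists covered the microRNA pathway, mRNA decay factors, textbook targets of let-7, miR-17/20/93/106, miR-19, miR-200, miR-21, miR-15/16, miR-29 and miR-34, microRNA host transcripts, p53 targets, E2F cell cycle genes, interferon-stimulated genes, mesenchymal and epithelial genes, WNT, ATF4 and unfolded protein response, hypoxia, NF-kB, immediate early and YAP genes, cholesterol synthesis, cytosolic ribosome, replication-dependent histones, mitochondrially encoded genes, nuclear and RNA polymerase III noncoding RNAs, cancer-testis genes, and markers of fibroblasts, endothelium, blood and neural or embryonic kidney cells. List tests used cameraPR in limma 3.58.1 (R 4.3.3) on signed square roots of the score for the 27 lists with at least 5 measured members, with a preset correlation between genes of 0.01, an alternative of 0.05, and Benjamini-Hochberg adjustment over lists. A correlation estimated from libraries needs values per library and was not run. In 100 runs on scores shuffled across genes, a planted list was called in 72, and 10 of 2100 other list tests were called. Shuffling removes correlation between genes, so this rate cannot show how often lists whose members vary together are called falsely.

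For the seed test, 10967 protein-coding genes with mean expression of at least 1 (log2 CPM) were split by a 7-mer match to positions 2 to 8 of each family in the 3′ UTR. Genes with a site were compared with genes without within 20 bins of UTR length, or within 5 bins of GC content inside each length bin, by 10000 permutations of ranks, adjusted by Benjamini-Hochberg over the 26 families; 19 were taken as expressed in colorectal cells and 7 as controls. The transcript was the principal one with the longest 3′ UTR. That rule replaced the longest coding sequence after a first look, in which the chosen HMGA2 transcript lacked its let-7 sites; the earlier rule was kept as an alternative. In fold changes shuffled across genes, a planted shift of -0.10 came back as -0.097 and was found in 10 of 10 runs. There 15 of 250 other tests passed an unadjusted 0.05. Shuffling removes any link of fold changes with UTR length or GC content, so those runs do not test the matching.

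Genes raised or lowered in the knockout by at least 0.5 on the log2 scale formed 2 sets, tested in the FH-5xA minus FH-WT difference against 10000 random sets matched on mean expression. The sets come from parental and knockout libraries and the difference from the reconstituted ones. Alternatives tried were a false discovery rate of 0.01, an absolute log2 fold change of at least 1, a minimum mean expression of 1 or 3, centring on the median, other definitions of the knockout sets and of a reversed gene, 8-mer sites and the higher correlation. Added after the data were seen were leaving out chromosome 7, centring or matching on GC content, another variance for the difference and the other transcript rule. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.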

Results

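Whole-transcriptome RNA-seq was compared between 4 forms of HCT116, a human colorectal carcinoma line: parental cells, AGO2 knockout cells, and knockout cells given back FH-tagged AGO2, either wild type (FH-WT) or the 5xA mutant (FH-5xA). AGO2 is the Argonaute protein that microRNAs guide to target mRNAs, which are then repressed and degraded. The series asks which transcripts separate cells with wild-type AGO2 from cells with the mutant, in the setting of a phosphorylation cycle of Argonaute, with parental and knockout cells as controls. Each group had 3 libraries. The values come from the authors' deposited tables of group comparisons over 15074 genes, so the depth of each library is unknown. Mean expression ran from -0.95 to 12.96 with a median of 4.45 (log2 CPM). Errors are SEs derived from the deposited scores.

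AGO2 mRNA (ENSG00000123908, chromosome 8, 140520156 to 140635619, GRCh38) was lower in the knockout and higher again in both reconstituted lines. In the authors' deposited tables its log2 fold change was -0.35 ± 0.07 in knockout against parental cells, 0.75 ± 0.07 in FH-WT against knockout and 0.73 ± 0.07 in FH-5xA against knockout, with deposited false discovery rates of 1.4e-06, 1.0e-24 and 3.2e-24. The AGO2 transcript thus persisted in the knockout at a fold change of 1.28 below parental. Where the edit lies is not given in the sources used here, so the RNA level checks the direction of the labels and not the loss of protein. Against parental cells AGO2 was higher by 0.40 ± 0.07 in FH-WT and 0.38 ± 0.07 in FH-5xA in the authors' deposited tables. The derived difference between FH-5xA and FH-WT was -0.02 ± 0.07, with a Benjamini-Hochberg adjusted p of 0.92.

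Several core genes of silencing were higher in the knockout, although the microRNA pathway list as a whole did not pass its test (cameraPR adjusted p = 0.055; 11 of 22 higher and 3 lower, 12 and 3 adjusted over the list alone). In the authors' deposited table for knockout against parental, ANKRD52, a regulatory subunit of protein phosphatase 6, rose by 1.15 ± 0.13 and its catalytic partner PPP6C by 0.35 ± 0.08. The same deposited table by the authors had AGO4 at 0.59 ± 0.11, DICER1, the nuclease that matures microRNAs, at 0.55 ± 0.08 and TNRC6B, a GW182 scaffold protein, at 0.48 ± 0.08. Also called higher there, in the authors' deposited table, were TNRC6C at 0.43 ± 0.12, AGO3 at 0.41 ± 0.07, TNRC6A at 0.29 ± 0.08 and AGO1 at 0.26 ± 0.08. CSNK1A1, a casein kinase 1 gene, was at -0.06 ± 0.07 and was not called in the authors' deposited table. Of these, DICER1 fell by 0.42 ± 0.08 with FH-WT and by 0.62 ± 0.08 with FH-5xA, AGO4 fell by 0.48 ± 0.11 and 0.44 ± 0.11, and AGO1 fell by 0.27 ± 0.08 with either protein in the authors' deposited tables against knockout. PPP6C fell by 0.42 ± 0.09 and ANKRD52 by 0.38 ± 0.13 with FH-5xA, while FH-WT gave -0.19 ± 0.09 and -0.31 ± 0.13, neither of them called in the authors' deposited tables. No gene of this core group differed between FH-5xA and FH-WT; the derived differences closest to the threshold were -0.20 ± 0.08 for DICER1 and -0.23 ± 0.09 for PPP6C, each at a Benjamini-Hochberg adjusted p of 0.11.

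**Figure D1:**
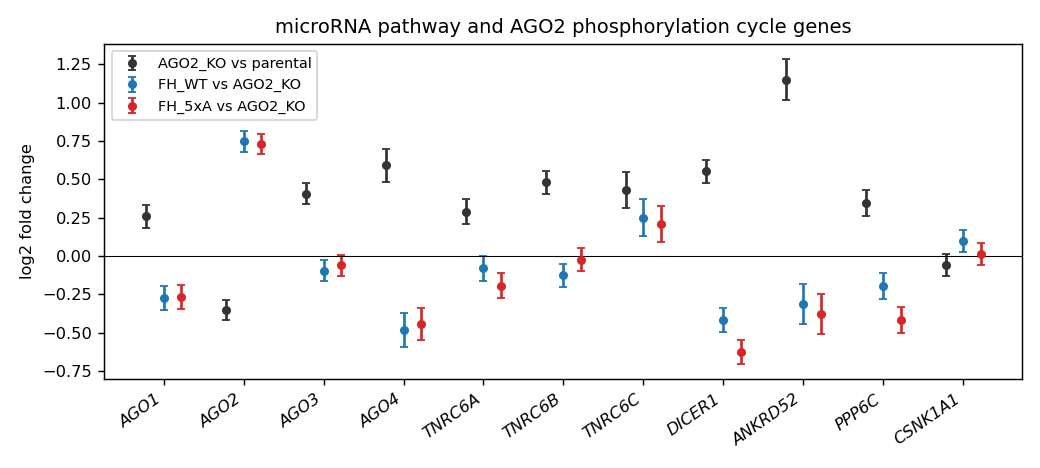
Log2 fold changes of the 11 core silencing genes in knockout against parental, FH-WT against knockout and FH-5xA against knockout; points are the values of the authors' deposited tables and bars are derived SEs. AGO2 moves from -0.35 in the knockout to rises of 0.75 and 0.73 on reconstitution.

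The knockout line differed broadly from parental cells. It is a single line that also carries the shift of chromosome 7 described below. Loss of AGO2 therefore cannot be told apart from other changes of that line. The knockout had more mRNA of NRP1, a coreceptor for semaphorins and VEGF (chromosome 10, 33177492 to 33336262), and of mesenchymal genes, p53 targets and interferon-stimulated genes. It had less mRNA of epithelial genes, E2F cell cycle genes, replication-dependent histones and genes of the ATF4 and unfolded protein response. Of 15074 genes, 6695 were called in the authors' deposited table, 3499 higher and 3196 lower, and 699 of them changed at least 2-fold.

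The largest rises in the authors' deposited table for knockout against parental were NRP1 at 5.46 ± 0.10, the long noncoding RNA SCAT8 at 4.66 ± 0.30, NOS1, a nitric oxide synthase, at 4.27 ± 0.43, CPA4, a carboxypeptidase, at 4.06 ± 0.13 and EYS at 3.93 ± 0.50. Next came the adhesion molecule CEACAM1 at 3.86 ± 0.34, the collagen COL17A1 at 3.35 ± 0.16, the laminin LAMA4 at 3.31 ± 0.14, VIM-AS1 at 3.16 ± 0.29 and LOXL4, a collagen crosslinking enzyme, at 3.13 ± 0.13 in the authors' deposited table. Among the largest falls there, the authors' deposited table gave MNS1 at -4.46 ± 0.21, CSTA, a protease inhibitor, at -3.79 ± 0.18, and GRHL2, a transcription factor of epithelial identity (chromosome 8, 101492432 to 101669726), at -3.38 ± 0.12. They also included the mucin-type glycosyltransferase GALNT3 at -2.58 ± 0.13, ATP2C2 at -2.54 ± 0.14 and GSDME, a pore-forming gasdermin, at -2.50 ± 0.19 in the authors' deposited table. ETV1, an ETS transcription factor (chromosome 7, 13891228 to 13991425), and ZNF615 were near zero in the knockout, so their fitted log2 values of -9.34 and -5.40 in the authors' deposited table depend on the prior count and are no bound. TWIST1 was likewise at the lowest fitted level in all 3 knockout-derived lines. NOS1 and EYS were near zero in parental cells, at fitted levels of 0.085 and 0.058 CPM, so their fitted rises depend on the prior count as well. SCAT8 and VIM-AS1 lie antisense to other genes and remain uncertain, as the strand used in counting is not known.

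Of the 27 lists tested, 17 passed an adjusted p of 0.05 in knockout against parental (cameraPR, limma). The p53 targets rose as a group (median 0.68, adjusted p = 1.26e-13): 19 of 26 members were called higher and 0 lower, and again 19 and 0 adjusted over the list alone. The cell cycle inhibitor CDKN1A was at 2.04 ± 0.11, TP53INP1 at 1.84 ± 0.11, BTG2 at 1.31 ± 0.11 and the death receptor FAS at 1.24 ± 0.10 in the authors' deposited table. E2F cell cycle genes fell (median -0.52, cameraPR adjusted p = 3.56e-11), with 22 of 26 members lower and 0 higher, or 23 and 0 adjusted over the list alone. The replication genes MCM4 and CDC6 were at -0.71 ± 0.07 and -0.69 ± 0.07 in the authors' deposited table. All 11 measured replication-dependent histones were lower (median -0.91, cameraPR adjusted p = 8.23e-07; also 11 adjusted over the list alone), although near-identical histone copies can share reads.

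Interferon-stimulated genes rose (median 0.69, cameraPR adjusted p = 2.03e-07), with 11 of 15 measured members higher and 0 lower by either adjustment, over all genes or adjusted over the list alone. The antiviral genes IFIT2 and IFIT1 were at 2.34 ± 0.14 and 1.89 ± 0.15 in the authors' deposited table. Mesenchymal genes rose (cameraPR adjusted p = 6.22e-06, median 0.53, 9 of 12 higher and 1 lower, likewise adjusted over the list alone), among them the epithelial repressor ZEB1 and VIM at 2.54 ± 0.17 in the authors' deposited table. TWIST1 went the other way and brought the mean of the list to 0.11. Epithelial genes fell (cameraPR adjusted p = 4.77e-07, median -0.46), with 8 of 15 lower and 0 higher, 9 and 0 adjusted over the list alone, including GRHL2, CLDN7 at -1.13 ± 0.11, the splicing factor ESRP1 at -1.06 ± 0.10 and the adhesion protein CDH1 at -0.97 ± 0.08 in the authors' deposited table. ATF4 and unfolded protein response genes fell (cameraPR adjusted p = 1.88e-07, median -0.40), 11 of 19 lower and 2 higher, 12 and 2 adjusted over the list alone. The serine synthesis gene PHGDH was at -1.46 ± 0.07, TRIB3 at -1.42 ± 0.10 and asparagine synthetase ASNS at -1.29 ± 0.09 in the authors' deposited table.

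YAP targets rose (median 0.39, cameraPR adjusted p = 1.20e-06; 9 of 13 higher and 0 lower, 9 and 1 adjusted over the list alone). NF-kB genes rose (median 0.46, cameraPR adjusted p = 0.000756; 7 of 11 higher and 0 lower, 8 and 0 adjusted over the list alone), as did hypoxia genes (median 0.46, cameraPR adjusted p = 0.00495; 10 of 19 higher and 3 lower by either adjustment, over all genes or adjusted over the list alone). Cholesterol synthesis genes fell (median -0.37, cameraPR adjusted p = 0.000791; 14 of 24 lower and 2 higher, unchanged when adjusted over the list alone). Cytosolic ribosomal protein genes fell as well (median -0.29, cameraPR adjusted p = 0.00279; 14 of 22 lower and 0 higher, 16 and 0 adjusted over the list alone).

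Textbook microRNA targets rose for 5 families. Targets of the miR-17 family had a median of 0.38 (cameraPR adjusted p = 3.08e-05; 11 of 18 higher and 4 lower, 12 and 4 adjusted over the list alone). Targets of miR-19 had a median of 0.42 (cameraPR adjusted p = 0.000114; 10 of 14 higher and 0 lower, also adjusted over the list alone) and targets of miR-200 a median of 0.10 (cameraPR adjusted p = 0.0106; 6 of 16 higher and 1 lower, also adjusted over the list alone). For miR-21 targets (median 0.25; 9 of 18 higher and 3 lower, also adjusted over the list alone) the adjusted p was 0.0262, and adjusted p = 0.0861 with a correlation of 0.05. For miR-29 targets (median 0.39; 8 of 14 higher and 1 lower, also adjusted over the list alone) the adjusted p was 0.0302, and adjusted p = 0.0861 with a correlation of 0.05. BCL2L11, a proapoptotic gene, stood at 1.10 ± 0.11, STAT3 at 0.73 ± 0.07 and HMGA2, the classic let-7 target, at 0.93 ± 0.08 in the authors' deposited table. Lists overlap: CDKN1A and TP53INP1 are p53 targets and microRNA targets at once.

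The other 10 lists were not called in knockout against parental. Their cameraPR adjusted p was 0.055 for the microRNA pathway (median 0.23), 0.0736 for immediate early genes (0.25), 0.0984 for miR-15/16 targets (-0.17), 0.175 for miR-34 targets (0.11), 0.221 for let-7 targets (0.05) and 0.531 for nuclear and polymerase III noncoding RNAs (-0.30). It was 0.648 for mRNA decay factors (0.10), for WNT targets (0.15) and for mitochondrially encoded genes (0.45), and 0.966 for microRNA host transcripts (0.09), where MIR17HG was at -0.54 ± 0.14 in the authors' deposited table. Without chromosome 7, which shifted as a block, the microRNA pathway list reached an adjusted p of 0.0354 and the immediate early list 0.05. Markers of other cell types were mostly absent from the tables: 0 of 15 for blood, 2 of 11 for endothelium, 4 of 14 for fibroblasts and 4 of 14 for neural or embryonic kidney cells, and 2 of 20 cancer-testis genes were measured, too few for a test. Of those present, ACTA2 was at 1.41 ± 0.17 and PAX6 at -1.43 ± 0.20 in the authors' deposited table, while MAGEA3 at -0.13 ± 0.09 and ESAM at -0.05 ± 0.18 were not called there. Other called markers were PAX2 at 0.85, COL1A1 at 0.59 and TAGLN at -0.60 in the authors' deposited table, so the markers did not all move 1 way.

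**Figure D2:**
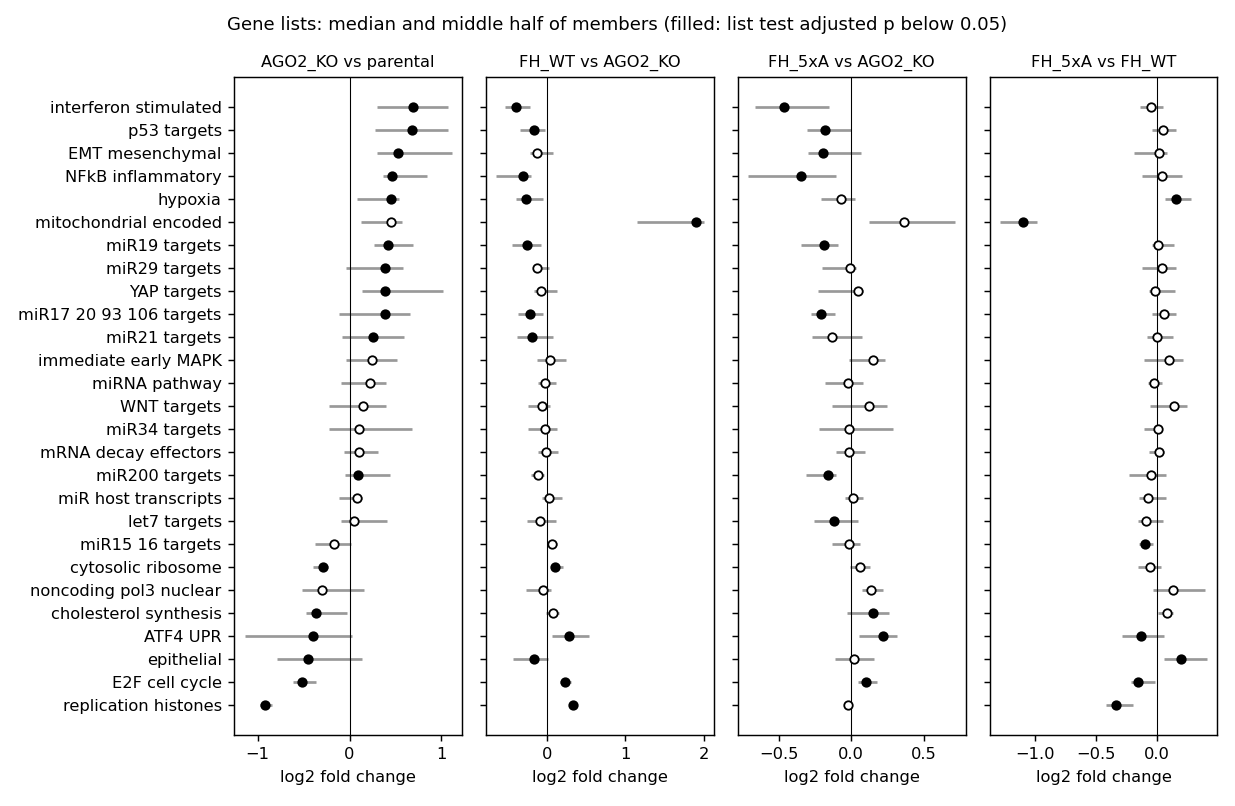
Median log2 fold change of the members of each tested gene list in 4 comparisons, with the middle 50% of members as bars and filled markers for lists that pass an adjusted p of 0.05 (cameraPR). p53 targets sit at 0.68 in knockout against parental and E2F cell cycle genes at -0.52, and both lie closer to 0 against the knockout.

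Chromosome 7 moved by position in the knockout. Its 189 measured genes from the start of the chromosome to 50 Mb had a median log2 fold change of -0.93 against parental (95% bootstrap interval -0.99 to -0.85), with 180 of them below 0. The 401 genes beyond 70 Mb had a median of 0.49 (0.45 to 0.53), with 361 above 0. Both reconstituted lines kept the pattern against parental, at -0.88 and 0.51 for FH-WT and -0.91 and 0.52 for FH-5xA. Against the knockout the left segment stood at 0.02 with FH-WT (-0.00088 to 0.057) and at 0.01 with FH-5xA. Among 273 other bins of 10000000 bases the largest absolute median was 0.42, for 77 genes on chromosome 6 from 20000001 to 30000000. ETV1, GSDME, TWIST1 and ITGB8 lie in the left part of chromosome 7 and CPA4, ASNS and RNY1 in the right part.

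**Figure D3:**
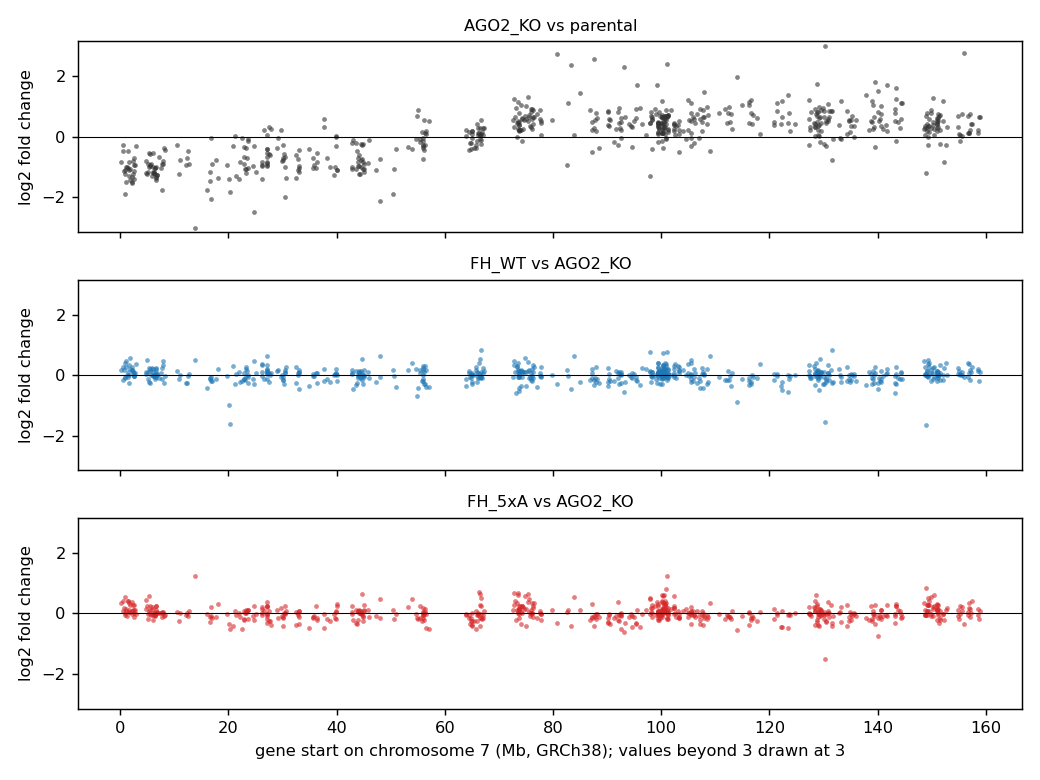
Log2 fold change of genes along chromosome 7 (position in Mb, GRCh38); each point is a gene, with the reconstituted lines against knockout in the lower panels. Genes up to 50 Mb lie around -0.93 in knockout against parental and genes beyond 70 Mb around 0.49, and both lie near 0 against the knockout.

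With wild-type AGO2 many of these groups moved opposite to their change in the knockout. Both comparisons share the 3 knockout libraries, so chance values of those libraries add to such a return, and their share was not simulated for the lists. In FH-WT against knockout, targets of the miR-17 family and of miR-19, p53 targets, interferon, hypoxia and NF-kB genes fell, while E2F, histone and ATF4 genes rose, and RNAs of the mitochondrial genome stood higher. The authors' deposited table had 1516 called genes, 634 higher and 882 lower, of which 75 changed at least 2-fold. The largest falls of the authors' deposited table included EHF, an epithelial ETS factor, the integrin ITGB8 at -1.62 ± 0.21, CPA4 at -1.55 ± 0.11, SNORA53, a small nucleolar RNA, at -1.42 ± 0.17, the glutamate receptor GRIN2B at -1.28 ± 0.16 and the RNA-binding protein CELF2 at -1.26 ± 0.17.

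Most of the largest rises with FH-WT were mitochondrial RNAs, led in the authors' deposited table by the ribosomal RNA MT-RNR2 at 3.21 ± 0.75, MT-ATP8 at 2.58 ± 0.67 and MT-ND2 at 2.55 ± 0.69. An unnamed long noncoding gene on chromosome 21 (ENSG00000281383) was at 9.49 ± 1.35 in the authors' deposited table, from a level near zero. These errors were wide: the median SE of the 20 mitochondrial genes was 0.488, against 0.0871 for other genes of similar or higher expression. Mitochondrial RNA made up 0.870% of fitted expression in parental, 1.29% in knockout, 3.91% in FH-WT and 1.99% in FH-5xA, and MT-RNR2, a ribosomal RNA that depletion can leave in varying amounts, made up 1.88% in FH-WT. The list of 13 mitochondrially encoded genes passed (median 1.91, cameraPR adjusted p = 1.85e-07), with 8 higher and 0 lower, 10 and 0 adjusted over the list alone. These RNAs can vary together between libraries, which the preset correlation of the test does not cover. The nuclear copy MTATP6P1 is nearly identical to mitochondrial sequence and remains uncertain.

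In all, 13 lists passed in FH-WT against knockout (cameraPR). E2F genes rose (median 0.23, adjusted p = 1.67e-10; 11 of 26 higher and 0 lower, 18 and 0 adjusted over the list alone). ATF4 and unfolded protein response genes rose (median 0.29, adjusted p = 1.66e-10; 8 of 19 higher and 0 lower, 9 and 0 adjusted over the list alone), as did histones (median 0.33, adjusted p = 0.000635; 2 of 11 and 0, 3 and 0 adjusted over the list alone). Falls were found for interferon genes (median -0.40, adjusted p = 4.51e-09; 8 of 15 lower and 0 higher, 9 and 0 adjusted over the list alone) and p53 targets (median -0.16, adjusted p = 7.21e-07; 10 of 26 and 0, also adjusted over the list alone). Hypoxia genes fell too (median -0.27, adjusted p = 2.64e-06; 8 of 19 and 0, 9 and 0 adjusted over the list alone), and so did NF-kB genes (median -0.31, adjusted p = 2.64e-06; 5 of 11 lower and 0 higher, 6 and 0 adjusted over the list alone). Targets of the miR-17 family (median -0.21, adjusted p = 2.64e-06; 8 of 18 lower and 0 higher, 9 and 0 adjusted over the list alone) fell. So did targets of miR-19 (median -0.26, adjusted p = 7.71e-05; 5 of 14 and 0, also adjusted over the list alone) and miR-21 (median -0.19, adjusted p = 0.00915; 7 of 18 and 1, 8 and 1 adjusted over the list alone). TP53INP1 at -0.73 ± 0.11 and the receptor TGFBR2 at -0.54 ± 0.09 are examples in the authors' deposited table. The let-7 target HMGA2 also fell, by 0.49 ± 0.08 in the authors' deposited table, while the list of let-7 targets did not pass (median -0.085, adjusted p = 0.279; 3 of 21 higher and 4 lower, 3 and 5 adjusted over the list alone). CHAC1 at 1.18 ± 0.19 and ASNS at 0.78 ± 0.09 are examples of rises in the authors' deposited table. Epithelial genes did not return but fell further (median -0.17, adjusted p = 0.0112; 3 of 15 lower and 0 higher, 5 and 0 adjusted over the list alone), with CDH1 at -0.67 ± 0.10 in the authors' deposited table. Ribosomal protein genes had a median of 0.11 and an adjusted p of 0.0179, with 0 of 22 members called by either adjustment, adjusted over the list alone included; the list gave adjusted p = 0.0905 with a correlation of 0.05.

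Interferon, p53 and microRNA target groups were also lower in FH-5xA than in the knockout. The knockout libraries are again shared with the comparison that defined their rise, so chance values of those libraries add to such falls. No group carried the tag or a vector alone. An effect of either AGO2 protein therefore cannot be told apart from other changes of its line. In FH-5xA against knockout, the authors' deposited table had 1699 called genes, 759 higher and 940 lower, and 85 changed at least 2-fold. The largest falls were the kinase DCLK1 at -1.71 ± 0.27, the angiogenic factor ANGPT2 at -1.52 ± 0.12, CPA4 at -1.49 ± 0.11 and the collagen COL13A1 at -1.46 ± 0.21 in the authors' deposited table. VSNL1 stood at -1.31 ± 0.12, SNORA53 at -1.30 ± 0.16 and TLR3, a sensor of double-stranded RNA, at -1.24 ± 0.13 in the authors' deposited table. The noncoding gene ENSG00000281383 rose here too, by 6.95 ± 1.22 in the authors' deposited table, again from a level near zero and with a wide error. Other rises in the authors' deposited table included the ubiquitin ligase gene RNF208 at 1.76 ± 0.36, the noncoding RNA LNCAROD at 1.56 ± 0.14, ATN1 at 1.35 ± 0.36, the chromatin gene BICRA at 1.29 ± 0.24 and the growth factor IGF2 at 1.28 ± 0.31. Fold changes in this comparison rose with the GC content of the transcript (Spearman 0.445 across 10967 genes, which are not independent replicates), against 0.148 for FH-WT against knockout and -0.00674 for knockout against parental. With fold changes centred within GC bins 1282 genes were called.

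With FH-5xA, 11 lists passed (cameraPR). Interferon genes fell (median -0.46, adjusted p = 1.87e-11; 9 of 15 lower and 0 higher, also adjusted over the list alone), with IFIT2 at -1.12 ± 0.13 in the authors' deposited table. NF-kB genes (median -0.34, adjusted p = 2.08e-05; 5 of 11 and 0, also adjusted over the list alone) and p53 targets (median -0.18, adjusted p = 0.000217; 10 of 26 and 0, also adjusted over the list alone) fell. So did targets of the miR-17 family (median -0.21, adjusted p = 0.000217; 7 of 18 lower and 1 higher, 8 and 1 adjusted over the list alone). Targets of miR-200 fell (median -0.16, adjusted p = 0.000261; 5 of 16 lower and 1 higher, 6 and 1 adjusted over the list alone). Falls were also found for targets of miR-19 (median -0.19, adjusted p = 0.00101; 4 of 14 and 0, also adjusted over the list alone) and for let-7 targets (median -0.12, adjusted p = 0.00549; 4 of 21 and 0, also adjusted over the list alone), with HMGA2 at -0.77 ± 0.08 in the authors' deposited table. Mesenchymal genes fell (median -0.19, adjusted p = 0.0131; 5 of 12 lower and 1 higher, 6 and 1 adjusted over the list alone), among them the matrix protein FN1 at -0.76 ± 0.13 in the authors' deposited table. ATF4 genes (median 0.22, adjusted p = 0.000217; 5 of 19 higher and 0 lower, 6 and 0 adjusted over the list alone) and cholesterol synthesis genes (median 0.15, adjusted p = 0.0049; 5 of 24 and 0, also adjusted over the list alone) rose. E2F genes had a median of 0.10 (2 of 26 higher and 0 lower, also adjusted over the list alone) and an adjusted p of 0.00954, with adjusted p = 0.0727 with a correlation of 0.05. DKK1, a secreted WNT inhibitor, rose by 1.04 ± 0.11 in the authors' deposited table.

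The reconstitutions shared many genes. Of the genes called against the knockout, 158 were higher and 455 lower with both proteins, where independent lists would share 31.9 and 55.0, and 0 were called in opposite directions. Simulated groups without any effect, compared with the same knockout libraries, shared 0 calls on average. With no effects hardly any gene passes the threshold, so that count cannot show how much of the overlap comes from the shared libraries. Across 13260 genes the fold changes correlated with Pearson r = 0.606 and Spearman rho = 0.533, against 0.476 and 0.449 in that simulation, and the covariance was 0.0378 against 0.00924, a difference of 0.0285; genes are not independent replicates. Part of the excess overlap may come from the shared knockout libraries, which were not split.

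Neither protein restored most of the genes changed in the knockout. Of 1804 genes raised in the knockout by at least 0.5, 384 (21.3%) fell significantly with FH-WT and 313 (17.4%) with FH-5xA. Of these, 202 fell with both, 182 with FH-WT alone and 111 with FH-5xA alone (exact binomial test on the genes that differ, two-sided p = 3.99e-05, as a description across genes). Of 1259 genes lowered, 187 (14.9%) rose with FH-WT and 9.93% with FH-5xA, 139 and 77 of them alone (exact binomial p = 2.95e-05). Of the raised genes, 23 rose further with FH-WT and 108 with FH-5xA, and 377 and 194 were not called against parental. Of the lowered genes, 32 and 33 fell further, and 295 and 262 were not called against parental. Median returns were -0.19 and -0.09 for the raised genes, whose median rise was 0.75, and 0.16 and 0.12 for the lowered genes, whose median was -0.70. In simulated FH-WT groups with no effect 0 raised genes were reversed (lowered genes and FH-5xA were not counted there). Without effects hardly any gene passes the threshold, so that 0 cannot tell how many of the 384 come from the shared libraries. Median returns in that simulation were -0.025 and 0.04 from the shared knockout libraries alone. The difference in raised genes, 3.94 percentage points, was 1.57 at a false discovery rate of 0.01 (exact p = 0.0694). It was 5.88 when a return of at least 50% counted as reversal (exact p = 6.8e-11). The difference in lowered genes was 2.93 at 0.01 (exact p = 0.00071) and 2.22 under the 50% rule (exact p = 0.0964).

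The reconstituted lines remained far from parental cells. FH-WT against parental had 5180 called genes in the authors' deposited table, 2755 higher and 2425 lower, 627 of them at least 2-fold. FH-5xA against parental had 6602, of which 3449 were higher and 3153 lower and 834 changed at least 2-fold in the authors' deposited table. NRP1 stayed at 5.25 ± 0.10 and 5.05 ± 0.10, GRHL2 at -3.86 ± 0.13 and -3.26 ± 0.12, and CDKN1A at 1.57 ± 0.11 and 1.61 ± 0.11 in the authors' deposited tables for FH-WT and FH-5xA. Likewise ZEB1 stayed at 2.15 ± 0.10 and 1.70 ± 0.10 and ANKRD52 at 0.84 ± 0.14 and 0.77 ± 0.13 in the authors' deposited tables. DICER1 was not called in either, at 0.13 ± 0.08 and -0.07 ± 0.08 in the authors' deposited tables.

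Of the lists, 15 passed in FH-WT against parental and 12 in FH-5xA against parental (cameraPR), and 7 of each passed with a correlation of 0.05. Those 7 included p53 targets (medians 0.43 and 0.51, adjusted p = 1.08e-08 and 4.43e-08), E2F genes (-0.30 and -0.42, adjusted p = 5.53e-05 and 1.09e-07), and epithelial genes (-0.53 and -0.37, adjusted p = 1.31e-12 and 2.21e-06). They also included YAP targets (0.45 and 0.42, adjusted p = 1.99e-06 and 2.35e-06), histones (-0.60 and -0.94, adjusted p = 0.000179 and 7.23e-07) and mesenchymal genes (0.55 and 0.58, adjusted p = 2.68e-05 and 0.00127), whose mean lay near 0 in both because TWIST1 stayed at the lowest level. The seventh was the mitochondrial list in FH-WT (median 2.10, adjusted p = 0.00123) and the ATF4 list in FH-5xA (-0.25, adjusted p = 0.000738). Mitochondrial RNAs can vary together between libraries, which the higher preset correlation may not cover either. Lists that lost their call in FH-WT against parental were the microRNA pathway (adjusted p = 0.134 with a correlation of 0.05), miR-17 family and miR-19 targets (adjusted p = 0.108 with a correlation of 0.05 for both), and interferon and ATF4 genes (adjusted p = 0.0752 with a correlation of 0.05 for both). So were cholesterol synthesis (adjusted p = 0.0632 with a correlation of 0.05), immediate early genes (adjusted p = 0.0882 with a correlation of 0.05) and ribosomal protein genes (adjusted p = 0.138 with a correlation of 0.05). In FH-5xA against parental these were the miR-17 family, miR-19 and ribosomal protein lists (adjusted p = 0.114 with a correlation of 0.05 for all 3), miR-15/16 targets (adjusted p = 0.117 with a correlation of 0.05) and immediate early genes (adjusted p = 0.0631 with a correlation of 0.05).

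The comparison at the centre of the study, FH-5xA against FH-WT, gave a smaller change. By the list tests, cells with 5xA AGO2 had more mRNA of epithelial and hypoxia genes than cells with the wild-type protein. They had less of E2F cell cycle genes and histones. Few members of these lists were called singly. The tests rest on a preset correlation between genes, and members may vary together more strongly between wells. The derived test called 620 of 15072 genes, 299 higher and 321 lower, and 20 of them differed at least 2-fold. The median absolute difference of the called genes was 0.43. Centred within GC bins, 434 genes were called, of which 371 were among the 620.

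The metallothioneins MT2A at -1.32 ± 0.31, MT1E at -1.30 ± 0.17 and MT1X at -0.89 ± 0.22, metal-binding proteins whose near-identical copies can share reads, were among the largest falls in FH-5xA relative to FH-WT, as was CSTA at -0.97 ± 0.28. The small RNAs SNORD11B at -1.16 ± 0.33 and RNU4ATAC at -1.15 ± 0.24 and the processed pseudogenes ATP5MKP1 at -0.99 ± 0.26, SETP3 at -0.85 ± 0.20 and SUMO2P6 at -0.85 ± 0.24, which share sequence with their parent genes, were also lower. ITGB8 was higher by 1.09 ± 0.21, the peptide precursor NPW by 1.89 ± 0.48 and the mitochondrial fission gene MTFP1 by 1.23 ± 0.32. So were the cytochrome CYP4F12 by 1.04 ± 0.27, the Y RNA RNY1 by 2.48 ± 0.57 and the spliceosomal RNU5B-1 by 1.31 ± 0.31. RNF208 at 1.31 ± 0.37 and MEGF6 at 1.05 ± 0.32 lost their call, as did the pseudogene HMGN2P4, after centring within GC bins. ZNF615, at 4.64 ± 1.20, was near zero in every knockout-derived line.

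Of the 27 lists, 7 passed for FH-5xA against FH-WT (cameraPR). Epithelial genes were higher (median 0.20, adjusted p = 0.000137; 4 of 15 higher and 0 lower, 6 and 0 adjusted over the list alone), with GRHL2 at 0.60 ± 0.15, ELF3 at 0.46 ± 0.10, CDH1 at 0.43 ± 0.10 and ESRP1 at 0.33 ± 0.10. Hypoxia genes were higher (median 0.16, adjusted p = 0.00351; 3 of 19 and 0, also adjusted over the list alone), including ALDOC at 0.39 ± 0.12 and BNIP3 at 0.37 ± 0.11. E2F genes were lower (median -0.16, adjusted p = 0.00012; 3 of 26 lower and 0 higher, 10 and 0 adjusted over the list alone), with AURKA at -0.25 ± 0.07. Histones were lower (median -0.34, adjusted p = 0.000137; 1 of 11 and 0, 3 and 0 adjusted over the list alone), with H2BC21 at -0.54 ± 0.11. The mitochondrial list was lower (median -1.10, adjusted p = 1.46e-05), with 0 of 13 genes called over all genes and 5 lower adjusted over the list alone. These RNAs come from a single genome and can vary together between libraries, which the preset correlation of the test does not cover, so no fall is read from it. ATF4 genes had a median of -0.13 (4 of 19 lower and 0 higher, 7 and 1 adjusted over the list alone) and an adjusted p of 0.00686, with adjusted p = 0.0561 with a correlation of 0.05. Targets of miR-15/16 had a median of -0.10 (0 of 14 called, 3 lower adjusted over the list alone) and an adjusted p of 0.0229, with adjusted p = 0.088 with a correlation of 0.05; without chromosome 7 it was 0.0643.

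The target lists of the miR-17 family, miR-19 and miR-21, which fell with FH-WT, did not pass between FH-5xA and FH-WT, at medians of 0.05, 0.0072 and 0.00040 and cameraPR adjusted p of 0.49, 0.611 and 0.574. Targets of let-7 stood at -0.09 with an adjusted p of 0.0766. Among single targets HMGA2 was lower in FH-5xA, at -0.28 ± 0.08, as were ZEB1 at -0.45 ± 0.09 and RBL1, a pocket protein, at -0.34 ± 0.08, while STAT3 was higher, at 0.23 ± 0.07.

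As a set, the 1804 genes raised in the knockout were higher in FH-5xA than in FH-WT. Their median difference was 0.097, against 0.016 in random sets matched on expression, an excess of 0.081, and 69.1% of them lay above 0 against 49.2% of other genes. The permutation p was 0.0001, the smallest that 10000 sets can give. The permutation p-values for these sets rest on random draws of genes, treated as independent. They do not measure the spread between libraries or lines. The 1259 lowered genes had a median of -0.031, an excess of -0.057 over their random sets (permutation p = 0.0001, again the smallest possible), and 44.5% lay above 0. For lowered genes chosen at a false discovery rate of 0.01 and a log2 fold change of 1 the excess was -0.021 (permutation p = 0.212). Their own median was 0.012, and 52.0% lay above 0. Across 13260 genes the knockout effect and the FH-5xA minus FH-WT difference, which come from separate libraries, had a Spearman correlation of 0.208; genes are not independent replicates.

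**Figure D4:**
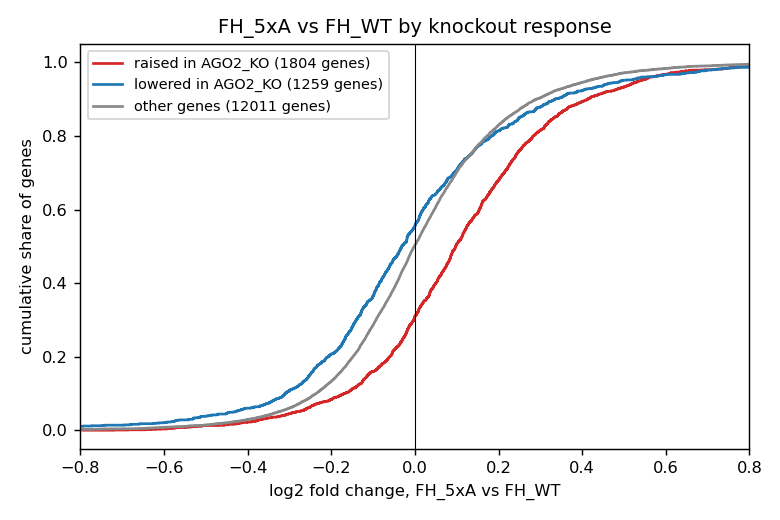
Cumulative share of genes by FH-5xA minus FH-WT log2 difference for genes raised, lowered or in neither set in knockout against parental. The median is 0.097 for the 1804 raised genes and -0.031 for the 1259 lowered genes.

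Genes with microRNA seed sites in their 3′ UTRs showed small shifts, and the control families did not stay clear of them. In knockout against parental, 6 of 19 expressed and 2 of 7 control families were called higher when matched on UTR length. Matched on GC content as well, a setting added after the data were seen, 5 expressed and 0 control families were called. All 7 controls still lay above 0 there, with a median shift of 0.025 against 0.018 for the expressed families. Genes with a miR-19 site (1616 of 10967) were higher by 0.051 ± 0.013 and genes with a miR-130 site (1720) by 0.050 ± 0.013, each at a permutation p of 0.0001, the smallest that 10000 permutations can give, and a Benjamini-Hochberg adjusted p of 0.0013. With FH-WT, under the GC match, 6 expressed families shifted down, miR-19 at -0.024 ± 0.0062 and miR-130 at -0.017 ± 0.0061, but so did 2 control families, miR-124 at -0.015 ± 0.0060 and miR-1 at -0.014 ± 0.0066. With FH-5xA 6 expressed families and 0 controls were called lower under that match, miR-19 at -0.021 ± 0.0061 and miR-130 at -0.020 ± 0.0060. The controls were taken as not expressed from textbook knowledge, and microRNA levels were not analysed here.

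Between FH-5xA and FH-WT only miR-27 sites passed once GC content was matched, at 0.015 ± 0.0051 (Benjamini-Hochberg adjusted p = 0.0104), of 19 expressed families. Matched on UTR length alone, 10 expressed and 2 control families passed, 4 and 2 of them higher. For FH-5xA against parental cells, 2 expressed families were higher and 4 lower when matched on UTR length alone, with 2 control families higher, and 0 expressed families were called with 8-mer sites. Under the GC match, 4 expressed families were higher in FH-WT and 3 in FH-5xA against parental, with 1 control family, miR-122, at 0.029 ± 0.015 in FH-WT and 0 in FH-5xA.

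**Figure D5:**
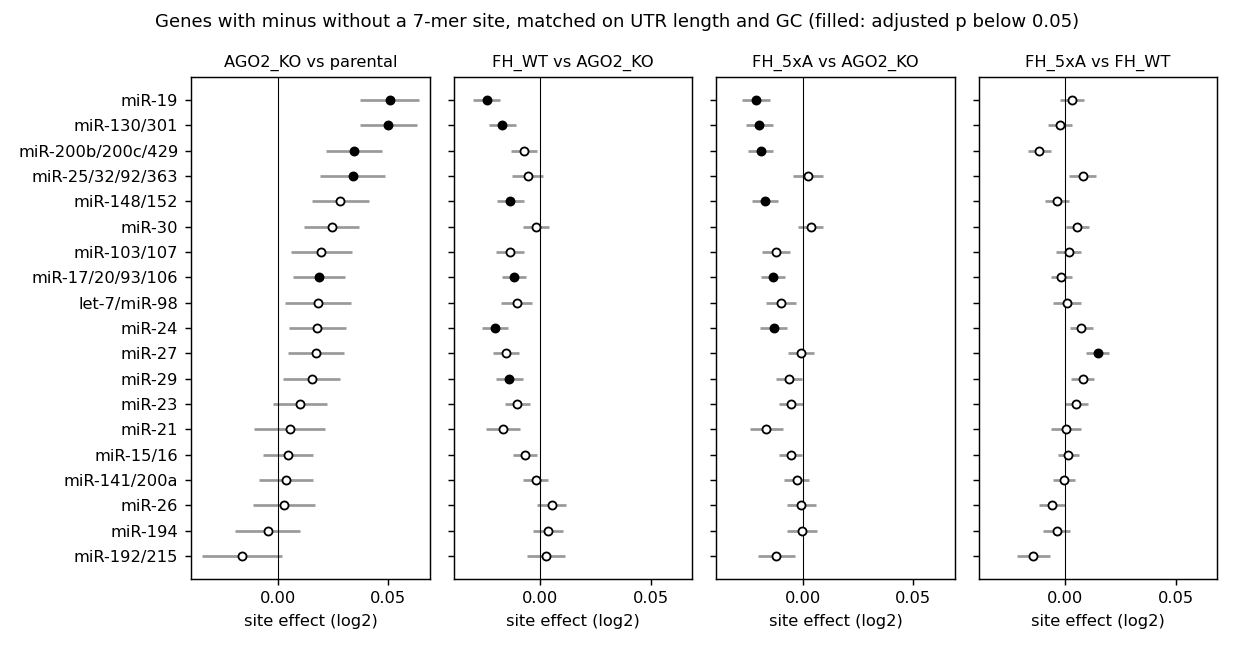
Shift in log2 fold change of genes with a 7-mer seed site against genes without, matched on 3′ UTR length and GC content, for the 19 expressed microRNA families in 4 comparisons; bars are SEs. For miR-19 the shift is 0.051 in knockout against parental, -0.024 with FH-WT and -0.021 with FH-5xA.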

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

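All tests of explanations in this part were chosen after the patterns were seen, and the predictions on expression bins and on chromosome 7 segments were also written after their own results were seen. The shift of the raised genes, the lists and the single genes stand here because a test of the difference between the effects of FH-5xA and FH-WT, both measured against the knockout, passed its threshold. The trend with GC content and the shift of chromosome 7 were noticed in the fold changes and are added to them.

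Genes raised in the knockout stood higher in FH-5xA than in FH-WT, with a median of 0.097 over the set. Matching random sets of protein-coding genes on expression, GC content and 3′ UTR length left an excess of 0.062 (1470 genes, 95% of random medians between 0.019 and 0.038), and leaving out chromosome 7 left 0.087 (random medians 0.0095 to 0.032), so neither accounts for the shift by itself. Weaker repression by 5xA of genes with sites of the 5 families that passed in the knockout cannot be told apart from no such effect: raised genes with a site (755) differed from those without (558) by -0.018 (95% interval -0.046 to 0.0098). The bound set earlier did not decide this, because FH-WT itself moved raised genes with a site no further than those without, at 0.0098 (-0.026 to 0.045), and the reading was changed after that result was seen.

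Differences rose with transcript GC content between FH-5xA and FH-WT (Spearman 0.324 over 10967 genes, which are not independent replicates) and fell about as strongly with mean expression (-0.332). A bias of library preparation could raise GC-rich RNA of any class; between the 2 reconstituted lines the correlation was 0.043 in 700 noncoding genes (95% interval -0.031 to 0.12) against 0.318 in 11110 coding genes and 0.293 in 1112 processed pseudogenes. Within 10 expression bins the mean correlation with GC was 0.24, so lower expression of GC-rich transcripts does not account for all of it, but it ran from 0.316, 0.381 and 0.378 in the 3 lowest bins to 0.128, 0.127 and 0.050 in the 3 highest and was nearly absent in the most abundant genes. Against the knockout, noncoding genes did follow GC content, at 0.237 (0.165 to 0.304) in FH-5xA and 0.206 (0.132 to 0.279) in FH-WT, beside 0.438 and 0.149 in coding genes. In knockout against parental the noncoding genes ran the other way, at -0.182 (-0.252 to -0.114), beside -0.012 in coding genes. All 3 comparisons share the knockout libraries. Between the reconstituted lines the noncoding genes thus showed no clear trend, but the processed pseudogenes followed GC content nearly as coding genes did. These classes were not matched on expression or GC range, so such a bias is not excluded there. A GC bias of both lines against the knockout stays open as well.

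The shift of chromosome 7 in the knockout persisted when AGO2 was given back. For the left segment the median was 0.020 (-0.00088 to 0.057) in FH-WT against knockout, where a full return would give 0.93. The 1259 genes lowered in the knockout returned by a median of only 0.16 with FH-WT. A missing return of the segment therefore cannot by itself exclude missing AGO2 as the cause. Of the genes in that segment, 95.2% lay below 0 in knockout against parental, more than a few strongly changed genes could give, and at least 94.2% did so in each of the 3 knockout-derived lines. A loss of the left and gain of the right part of the chromosome in the line from which all 3 derive would give this pattern; DNA was not analysed here.

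The derived test called 620 genes between FH-5xA and FH-WT. List medians that differed were 0.20 for epithelial genes, 0.16 for hypoxia genes, -0.16 for E2F genes and -0.34 for histones. The mitochondrially encoded list passed at a median of -1.10 with 0 of 13 members called. These RNAs can vary together between libraries, so no fall is read from it. The call was lost for ATF4 and unfolded protein response genes (median -0.13, cameraPR adjusted p = 0.0561 with a correlation of 0.05) and for miR-15/16 targets (median -0.10, cameraPR adjusted p = 0.088 with a correlation of 0.05 and 0.0643 without chromosome 7). Single genes called against the knockout that differed were RNY1 at 2.48, RNF208 at 1.31, ITGB8 at 1.09, CYP4F12 at 1.04, EHF at 0.83, BICRA at 0.76 and VSNL1 at -0.50. ZNF615 differed as well, at 4.64, but it was near zero in every knockout-derived line, so that value depends on the prior count.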

How the results depend on the processing

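The excess of raised and of lowered genes over random sets kept its sign under every alternative, and no list that passed changed direction when centred within GC bins. The balance of calls did turn: FH-5xA against FH-WT had 299 genes higher and 321 lower, but 97 and 85 at a false discovery rate of 0.01 and 14 and 6 at 2-fold. FH-5xA against knockout went from 759 and 940 to 53 and 32 at 2-fold. Expressed seed families for FH-5xA against parental went from 2 higher and 4 lower to 3 and 0 when matched on GC content. The alternatives that left out chromosome 7, used GC content, another variance or the other transcript rule were chosen after the result was seen. At an absolute log2 fold change of at least 1, called genes numbered 699 for knockout against parental, 75 and 85 for FH-WT and FH-5xA against knockout, 627 and 834 against parental, and 20 for FH-5xA against FH-WT. At a false discovery rate of 0.01 they were 688, 895 and 182 for FH-WT and FH-5xA against knockout and FH-5xA against FH-WT, where 0.05 gave 1516, 1699 and 620. Reversed genes at 0.01 with FH-WT and FH-5xA were 234 and 208 of the raised genes, 1.57 points apart (exact p = 0.0694). Of the lowered genes they were 87 and 54, 2.93 points apart (exact p = 0.00071). With a return of at least 50%, 317 and 211 raised genes were reversed, 5.88 points apart (exact p = 6.8e-11). Under that rule FH-5xA reversed 209 lowered genes, 2.22 points from FH-WT (exact p = 0.0964). The excess of lowered genes chosen at a false discovery rate of 0.01 and log2 1 was -0.021 (permutation p = 0.212), while their own median was 0.012. The excess of raised genes ran from 0.062 to 0.094 over all settings. With a correlation of 0.05, 7 lists were called for FH-WT and 7 for FH-5xA against parental, and 15 for knockout against parental. Expressed seed families called were 6, 3 and 1 for FH-5xA against knockout, parental and FH-WT when matched on GC content, where UTR length alone gave 12, 6 and 10. With the longest coding sequence they were 5, 1 and 6 for FH-WT against knockout, FH-WT against parental and FH-5xA against FH-WT. With 8-mer sites they were 0 for FH-5xA against parental and 3 for FH-5xA against FH-WT, and 6 for the latter at an expression of at least 3. For lost calls the cause was not tested, beyond the smaller number of genes that stricter thresholds leave. Smaller losses were found as well: FH-5xA against FH-WT had 434 genes called under centring within GC bins, and 5 lists in place of 7 with a correlation of 0.05. Over all comparisons 19 list calls were lost at that correlation and 56 kept. No paired analysis was possible because values per library were not analysed here. For that reason other size factors, no low-count filter, another count test, fits of 2 groups only, a replicate block and leaving out libraries in turn were not run, and what depth limits is unknown.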

Other observations

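No test in this part was chosen after the result was seen. Several gene groups outside the main comparisons held single genes that moved. In knockout against parental, in the authors' deposited table, the growth factor TGFB2 rose by 2.08 ± 0.25, and the hypoxia gene NDRG1 by 1.69 ± 0.11, and the sterol enzyme SQLE fell by 1.26 ± 0.07. The receptor kinase MET, on the right part of chromosome 7, stood at 1.22 ± 0.08 in the authors' deposited table, and the nuclear noncoding RNA NEAT1 at 0.78 ± 0.10.

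Between FH-5xA and FH-WT the derived differences included SOX9, a transcription factor of intestinal crypts, at 0.54 ± 0.11, NEAT1 at 0.52 ± 0.10, the host transcript MIR31HG at 0.96 ± 0.26, the collagen COL1A1 at 0.79 ± 0.23 and VIM at -0.69 ± 0.15.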
